A study of Pimephales promelas with 16 samples.

How the data were processed

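Total RNA from the livers of 16 male fathead minnows, 8 control and 8 exposed to EE2, was extracted with Trizol, labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. The spot intensity values were made with Agilent Feature Extraction 11.0.1.1, per the file headers, which subtracts background and removes spatial trends without normalizing between arrays. The submitters' processing notes name limma, with no version. The deposited value table holds log2 values whose columns have nearly the same distribution, with medians from 6.10 to 6.11, and each column ranks as the background-subtracted median signal of its own array (rank correlation 1). Its scale was read as log2 from its range, and its normalization as quantile from the distributions; neither is stated in the sources used here.

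The main values were the log2 processed signal minus each array's 75th percentile over non-control probes. Spots that Feature Extraction marked as outliers (0.307%) were left out, and spots of one probe were averaged. A probe was tested when it was well above background on at least 8 of the 16 arrays. The file of EE2 replicate 17 held 32.9% of the features, and its 75th percentile of 214.9 was taken from its own header. On the complete arrays the header's percentile differed from that computed by at most 0.0243%. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with no covariate. Array-level measures were compared with exact two-sided permutation tests. The slide and the row of an array on the slide came from the file headers, and each slide was scanned as 1 unit, so slide and scan were 1 batch. No paired analysis was possible because the groups share no replicate numbers. Tanks are not among the labels used here, and the tests treated each liver as independent. If fish of one group shared tanks, the p-values could be too small.

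On simulated data for the comparison of all probes, with 38967 probes and 200 changed, limma recovered 75.8% of the 4-fold changes, 4.5% of the 2-fold changes and 0 of the 67 changes of 1.5-fold, with 2 false calls among 55. The simulated changes were few, and the share recovered depends on how many probes change. The simulated noise was independent between probes, without the structure that the real arrays share. The 2 false calls therefore do not measure the error rate in these data.

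The rule for named items, the tests and most of the alternatives were set before the data were examined. The rule took the largest rises and falls at an adjusted p below 0.05 with the same sign within both slides. Every probe's description is unknown in the files, and the gene table given (assembly fPimPro1.hap1.1) holds no sequences, so 0 probes were matched to a gene and at most 2 probes that rose and 2 that fell are printed. The planned tests of gene lists, and of relations between egg yolk protein transcripts and other genes among EE2 livers, were therefore not run. Alternatives covered normalization, background correction, the deposited values, the filter, the slide, the variance model, array weights and each array left out, and others were added after seeing the data. The array measures other than the first principal component and the spread between arrays, 8 of the 10 compared, were also chosen then.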

Results

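Liver transcript levels were measured in male fathead minnows (Pimephales promelas), a small freshwater fish used in toxicity testing. The exposed males were kept for 96 hours in water with 25 ng/L of 17α-ethinylestradiol (EE2), a synthetic estrogen. There were 8 control and 8 EE2 livers, described as biological replicates, with 1 one-colour array each. The dose and any solvent of the control water are not stated. The series is one laboratory's part of a comparison between laboratories, so both the response to EE2 and the spread between arrays were of interest. Each array carried 49849 probes of 60 bases with 44586 distinct sequences. Between 55.0% and 89.4% of the probes were well above background on an array. The scanner file of EE2 replicate 17 broke off after 20521 of the 62372 features, so many probes had 7 EE2 arrays in place of 8. For arrays, precision is limited by their number. The files do not pair the probes with gene names, so the changes are described by probe.

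EE2 was compared with control over all probes to ask which liver transcripts responded to the estrogen. Of 38967 probes tested, 1259 rose and 1151 fell with EE2, which is 6.18% of those tested. They held 1100 and 1038 distinct sequences. At least a 2-fold change was seen for 2062 probes, of which 1058 rose and 1004 fell. Among the called probes, 53 rose over 16-fold and 19 fell by as much. A fall ends at background, so a probe dim in controls had little room for a fall of that size. How much of the difference between 53 and 19 came from this limit was not tested. Some of these probes share a sequence, and distinct sequences were not counted by size of change. Between 4-fold and 16-fold, 254 rose and 203 fell. Most changes were smaller, with 751 rises and 782 falls of 2-fold to 4-fold. Every EE2 array with a value lay above every control for 447 of the probes that rose, and below every control for 245 of those that fell. Chance gives such a separation in one direction for 0.00777% of probes with 8 arrays against 8, and for 0.01554% with 8 against 7. These rates are for any probe, while the 447 and 245 were counted among probes called on the same arrays. Probes are also not independent of each other, so the rates do not say how large a count chance can give.

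**Figure D1:**
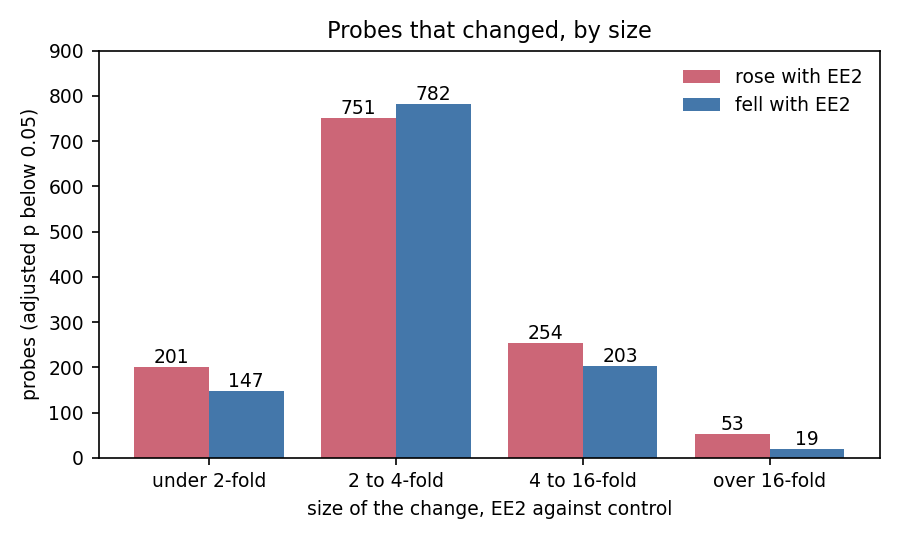
Bars give the number of probes (vertical axis) that rose or fell with EE2 at an adjusted p below 0.05, by the size of the change (horizontal axis). Over 16-fold, 53 probes rose and 19 fell, while between 2-fold and 4-fold the numbers were 751 and 782.

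The probes called as changed were more often bright than dim. Of the 9742 tested probes in the brightest of 4 equal sets by mean level, 668 rose and 608 fell, against 92 and 124 of the 9741 in the dimmest. The mean was taken over all arrays with EE2 included, so a rise itself moved a probe toward the brighter sets. Whether changes at dim probes were harder to call was not tested, so these counts do not show that bright transcripts responded more. The 53 probes that rose over 16-fold held 2.21% ± 0.30 (SD, n = 7) of the summed probe signal of an EE2 array and 0.147% ± 0.290 (SD, n = 8) of a control array, with no test because they were chosen by their rise. Control replicate 3 alone held 0.858%, and without it the control mean was 0.0458% ± 0.0425 (SD, n = 7). Loss to background was seen for 8 probes that were well above background on every control and not well above background on any EE2 array. They fell by at least 2.07-fold to at least 11.6-fold, with the EE2 mean taken on each array as the higher of the probe's own level and the lowest level among probes well above background. The reverse, signal well above background on every EE2 array with a value and on no control, was seen for 0 probes. The filter leaves out such a probe when it has 7 EE2 arrays, but with no filter the count was also 0, both for probes with 8 EE2 arrays and for those with 7. Allowing 1 exception, 8 probes rose with signal well above background on every EE2 array with a value and at most 1 control. For falls, 22 probes were so on every control and at most 1 EE2 array. The EE2 arrays had fewer probes well above background, 71.9% ± 10.9 (SD, n = 8) against 80.1% ± 7.12 (SD, n = 8) in controls (exact permutation p = 0.0984, adjusted p = 0.164). Whether this favoured losses over gains was not tested.

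On the 75th percentile scale the probe with the largest rise was SINGLET_45031, with the sequence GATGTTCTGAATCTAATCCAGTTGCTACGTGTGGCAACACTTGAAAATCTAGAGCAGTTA. Its level, as log2 signal minus the array's 75th percentile, was -0.63 ± 3.10 (SD, n = 8) in controls and 7.01 ± 0.81 (SD, n = 7) with EE2. The rise was 7.64 on the log2 scale (SE 1.04, limma adjusted p = 0.000208). SINGLET_7473, with the sequence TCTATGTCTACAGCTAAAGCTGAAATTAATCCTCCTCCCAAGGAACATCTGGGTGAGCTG, rose by 7.35 (SE 0.97, limma adjusted p = 0.000148), from 1.39 ± 2.93 (SD, n = 8) to 8.74 ± 0.53 (SD, n = 7). Control replicate 3 stood at 5.52 for SINGLET_45031 and 6.54 for SINGLET_7473, while the next highest controls were at 0.46 and 3.32. EE2 replicate 17 had no value for either. In the authors' processed values, which are on another scale, it stood at 13.24 for SINGLET_45031, below the highest control at 13.31, and at 14.98 for SINGLET_7473, above the highest control at 14.37, while the means of the other EE2 arrays were 14.80 and 16.48. On the same scale the probe with the largest fall was SINGLET_46373, with the sequence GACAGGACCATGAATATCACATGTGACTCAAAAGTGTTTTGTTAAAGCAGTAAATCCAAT. It fell by 4.99 (SE 0.83, limma adjusted p = 0.00104), from 4.30 ± 2.04 (SD, n = 8) to -0.69 ± 1.76 (SD, n = 8), and was well above background on 6 of the 8 EE2 arrays. SINGLET_9484, with the sequence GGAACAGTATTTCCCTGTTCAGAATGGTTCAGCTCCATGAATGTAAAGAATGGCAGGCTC, fell by 4.90 (SE 0.71, limma adjusted p = 0.00036), from 7.12 ± 1.92 (SD, n = 8) to 2.22 ± 1.01 (SD, n = 7). It differed by -6.72 within slide 1 and by -3.29 within slide 2. The order within each pair was not fixed: SINGLET_9484 fell by 5.13 and SINGLET_46373 fell by 4.67 in the authors' processed values, and under normexp SINGLET_7473 rose by 6.84 and SINGLET_45031 by 6.57. Single controls moved 3 of these values by over 1.5 times on the linear scale. Without control replicate 14, which was not well above background for either riser, SINGLET_45031 rose by 6.92 and SINGLET_7473 by 6.63. Without control replicate 3 the rises were 8.52 and 8.09, and SINGLET_46373 fell by 5.63.

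**Figure D2:**
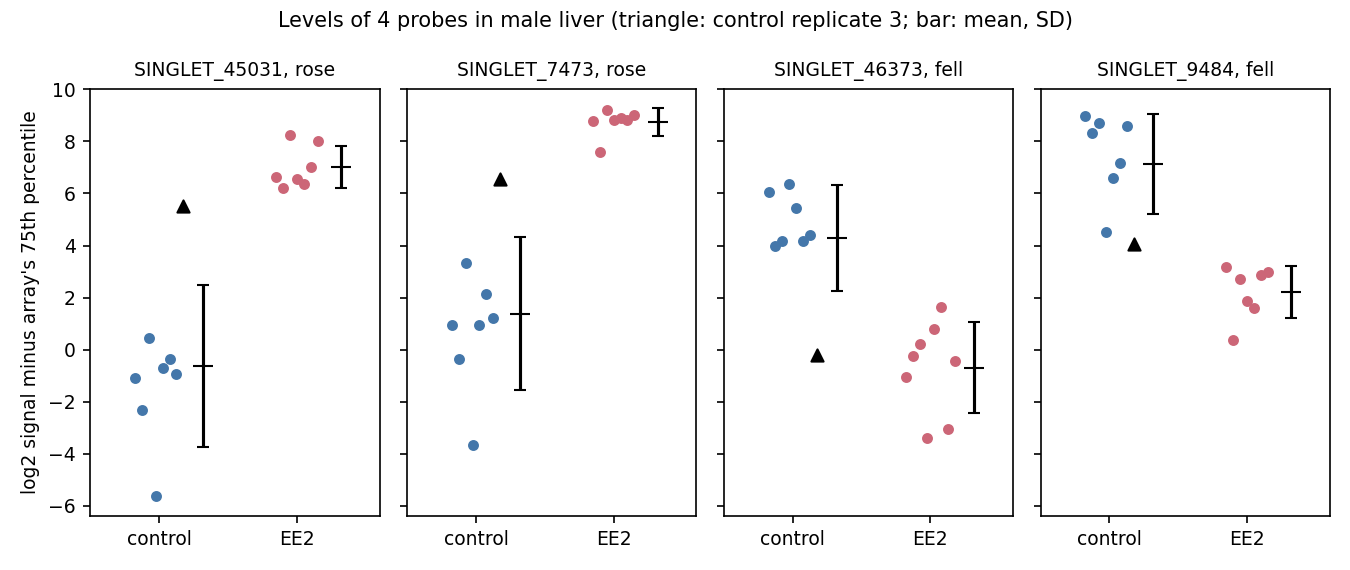
Points give the level of each array (vertical axis, log2 signal minus the array's 75th percentile) for the 8 controls and the EE2 livers, with bars for the mean and SD and a triangle for control replicate 3. SINGLET_45031 and SINGLET_7473 lie higher in each of the 7 EE2 livers with a value than in every control, and the triangle is the control nearest to the EE2 livers.

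The arrays lay on 2 slides, with 3 controls and 5 EE2 livers on slide 1 and 5 controls and 3 EE2 livers on slide 2. Most controls were in the upper row of a slide and most EE2 livers in the lower. EE2 replicates 5, 10, 16 and 17 were in column 4 of the slides, which held no control. An effect of the column was not tested and cannot be told apart from EE2 for these arrays. EE2 replicate 17 was on slide 2, so most probes had 2 EE2 values there. With the slide as a fixed block, limma called 2005 probes, of which 1051 rose. Within slide 1 alone 971 probes passed, and within slide 2 alone limma called 0, with 2452 at an unadjusted p under 0.05 (main comparison 7058). Slide 2 had few EE2 arrays, and its controls included replicates 3, 8 and 14, the controls farthest from the others of their group. Their root mean square deviations from the mean of the other controls were 1.06, 1.17 and 0.97 log2 units, against 0.64 to 0.79 for the remaining controls. What each contributed was not tested, and the 0 is not evidence that the slide lacked the changes. All 1259 rises and all 1151 falls kept their sign within each slide, although they were called on the same arrays. Over all 38967 probes 58.1% had the same sign in both slides, and the differences of the slides correlated at r = 0.53 across these probes, which are not independent replicates. The near balance of rises and falls was relative to each array's 75th percentile: scaled to the E1A spike-in, an alternative chosen after seeing the data, 10472 probes passed and 3.5% of them rose, against 52.2%, and the median difference of all probes lay at -0.78 on the log2 scale, against -0.06. That scale rests on only 4 spike-in probes.

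How far the total spread followed the treatment was asked with principal components of 14340 probes measured on all arrays. The first component held 31.6% of the variance and did not separate the groups, with scores of -5.32 ± 58.84 (SD, n = 8) in controls and 5.32 ± 57.14 (SD, n = 8) with EE2 (exact two-sided permutation p = 0.717, adjusted p = 0.797 over 10 array measures). The second, examined after the first was seen, held 15.97% and separated all 8 EE2 arrays from all 8 controls, at 37.0 ± 10.2 (SD, n = 8) against -37.0 ± 14.3 (SD, n = 8) (exact permutation p = 0.000155, the smallest the test can give; adjusted p = 0.000777). Its difference was 86.3 within slide 1 and 63.0 within slide 2. The first component itself differed between the groups in the authors' processed values and among probes above background on all arrays (exact permutation p = 0.000155 in both), and after normexp background correction (exact permutation p = 0.00171).

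**Figure D3:**
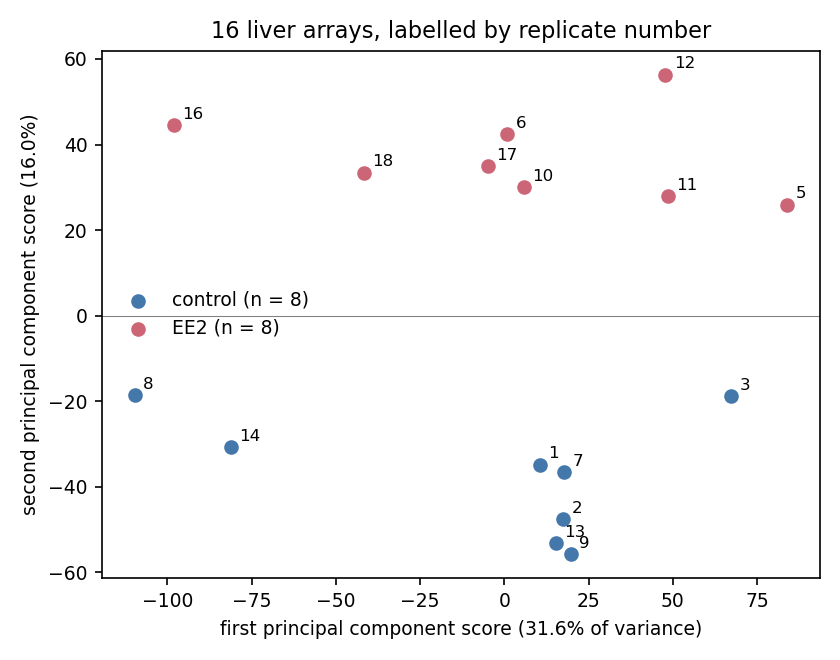
Each point is an array, by its score on the first (horizontal axis) and second (vertical axis) principal component, with its replicate number. The EE2 arrays lie above and the controls below a second-component score of 0, and control replicates 8 and 14 and EE2 replicate 16 lie at the low end of the first.

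The spread between arrays of one group was measured as the root mean square deviation of an array from the mean of the other arrays of its group. It was 0.827 ± 0.212 (SD, n = 8) log2 units in controls and 0.838 ± 0.175 (SD, n = 8) with EE2 (exact two-sided permutation p = 0.905, adjusted p = 0.905). The difference was 0.155 within slide 1 and -0.088 within slide 2. The test shuffled the values as they stood, although the values of one group are computed from each other, so its p is approximate. Probes with the same sequence on one array differed with an SD of 0.342, while the most alike pair of arrays differed with an SD of 0.719, which shows that no 2 arrays held the same values and does not test whether any 2 shared an RNA sample.

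The signal was more concentrated in the EE2 livers, a measure chosen after the data were examined. The 100 brightest probes of each array held 30.5% ± 2.04 (SD, n = 7) of its summed probe signal with EE2 and 25.2% ± 1.505 (SD, n = 8) in controls (exact two-sided permutation p = 0.000155, the smallest the test can give; adjusted p = 0.000777). The difference was 5.02 percentage points within slide 1 and 6.34 within slide 2, and 3.30 and 5.38 within the upper and lower array rows of the slides. The arrays' own 75th percentile signal was also lower with EE2, at 189.8 ± 52.1 (SD, n = 8) against 269.0 ± 48.7 (SD, n = 8) (exact permutation p = 0.0110, adjusted p = 0.0276), and the share was higher on arrays with a lower percentile (within groups r = -0.79). With log2 of the percentile as a covariate, tried after the data were seen, the EE2 difference was 2.97 percentage points (SE 0.79, linear model, n = 15 arrays) against 5.31 without it, so part of the difference went with the brightness of the arrays.

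**Figure D4:**
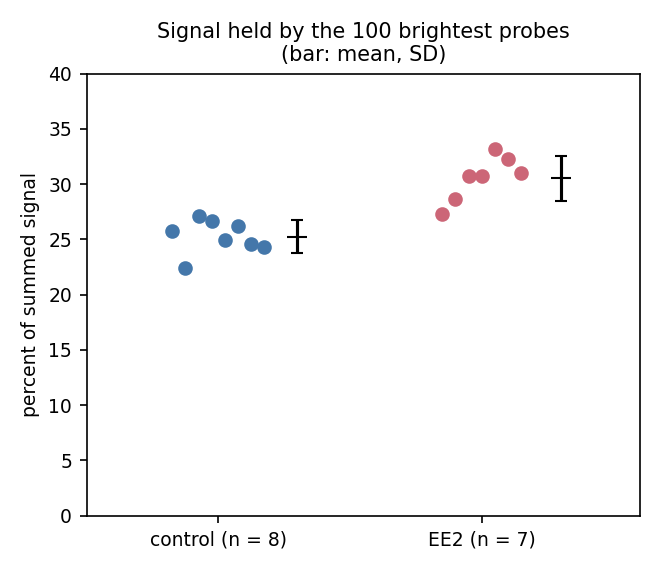
Points give, for each array, the percent of its summed probe signal held by its 100 brightest probes (vertical axis), with bars for the mean and SD of 8 controls and 7 EE2 livers. The EE2 mean is 30.5% and the control mean 25.2%.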

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

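The tests of a wrong label for control replicate 3, of no-target signal on the first component, in a split of the arrays and as a covariate, and of the slide row were chosen only after the result was seen. An array far from the others of its group was sought in 26 groups of values, of which chance gives about 1.3, and 3 were found. SINGLET_7473 stood at 7.58 in EE2 replicate 16, below the 6 other EE2 arrays with a value. In the authors' processed values, which also hold EE2 replicate 17, that array was lower, at 14.98 against 16.09 in EE2 replicate 16. SINGLET_46373 stood at -0.21 in control replicate 3, below the other controls. The median log2 signal of probes for ERCC and ETG control transcripts, called no-target probes here without a statement in the files that no such transcripts were added, was 5.57 in EE2 replicate 16, above the other EE2 arrays.

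Control replicate 3 lay between the other controls and the EE2 livers at the strongest risers. With probes called without the array under test, its median position between the other controls (0) and the EE2 arrays (1) was 0.343 over risers and 0.328 over fallers, while the EE2 arrays placed so lay at 0.938 ± 0.169 (SD, n = 8) and 0.883 ± 0.182 (SD, n = 8), with the lowest at 0.658 and 0.6. The 7 other controls lay at -0.088 to 0.118 over risers and at -0.168 to 0.356 over fallers, so over fallers it was within them. At risers over 16-fold it lay at 0.583, and the lowest EE2 array at 0.843. Its position, nearer to the controls than that of any EE2 array, argues against an EE2 liver carried under a control label. The correlations of levels across probes, which are not independent replicates, went the other way: its highest was with EE2 replicate 5 (r = 0.9597), above its highest with another control (r = 0.9368), and it was also the array closest to EE2 replicate 5, above that array's highest with another EE2 array (r = 0.9398). A wrong label is thus made less probable by the positions and is not ruled out by the correlations. Control replicate 3 and EE2 replicate 5 lay near each other on the first component (67.3 and 83.9) and the third (-71.6 and -56.3). Neither of these components separated the groups. On the second, which did, control replicate 3 scored -18.8, on the side of the controls (control replicate 8 at -18.5), and EE2 replicate 5 scored 26.0. What the correlations reflect was not tested. A share of EE2 RNA mixed in stays open: the share needed was 0.22, 0.162 and 0.18 over risers of 2-fold to 4-fold, 4-fold to 16-fold and over 16-fold, but 0.462 over fallers, a difference of 0.282 that lay within the largest value of the other controls there, 0.497. A response of that fish itself was not tested. Without this control limma called 2493 probes.

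Control replicates 8 and 14 and EE2 replicate 16 lay apart on the first principal component. With the score turned so that they were high, it followed the median no-target signal over the 16 arrays (Pearson r = 0.93, permutation p = 1e-05, the smallest the permutations can give; Spearman rho = 0.76, permutation p = 0.00105; adjusted p = 2e-05 and 0.00105 over 2 relations), also without the 2 farthest arrays (r = 0.85) and without the 3 brightest (r = 0.72). Across probes, which are not independent replicates, the loading followed GC content (rho = 0.45). Both values are consistent with more non-specific binding on those arrays, and the 2 explanations were not separated. No biological explanation was tested.

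The EE2 arrays were dimmer than controls against the E1A spike-in, by a log2 difference of -0.72 in the 75th percentile (exact permutation p = 0.00249, adjusted p = 0.00829; -0.93 within slide 1 and -0.53 within slide 2). With the slide row as a block the difference was -0.59 (SE 0.15), or 82.2% of that without it, which argues against the row as the whole cause. The summed signal over the spike-in differed by -0.47 (exact permutation p = 0.0651, adjusted p = 0.13, n = 8 and 7), by -0.78 within slide 1 and -0.13 within slide 2, and by -0.63 and -0.04 within the upper and lower rows, so its difference was not established. It was 64.5% of the 75th percentile's difference on the same arrays, so a few bright probes taking the signal cannot be told apart from a general fall, because this lay between the bounds set for either. The spike-in signal rests on only 4 probes. The amount of spike-in per RNA is not given in the sources used here, and an effect of EE2 on total transcript yield stays open and untested.

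In 100 splits of the 16 arrays 8 against 8, the real one included, of 6435 possible, 1 gave as many probes as the real 2410, and 1 as many as the real 2062 of at least 2-fold, the real one itself. The real split thus gave the most called probes of the splits drawn. This does not exclude chance, since few of the possible splits were drawn and a grouping described below gave more. The highest of the others was 0 in both cases. That 0 was close: the smallest adjusted p in the others was 0.056, and 4 of them gave more probes at an unadjusted p under 0.05 than the real 7058, up to 12094. A split that was not among these, of the 8 arrays brighter at no-target probes against the other 8, gave 2833 probes and 2634 of at least 2-fold, more than the treatment. The brighter arrays were control replicates 1, 7, 8, 9 and 14 and EE2 replicates 16, 17 and 18, so the split leaned with the groups. It was chosen after the data were seen, on a signal that the first component followed, so a large count was likely. It points to a structure of the arrays other than the treatment, though not fully apart from the groups. With the no-target signal as a covariate, limma called 4085 probes for EE2. Splits by slide and by slide row each gave 0 (2194 and 1601 at an unadjusted p under 0.05).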

How the results depend on the processing

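The alternatives with the slide row, the spike-in, the no-target signal, distinct sequences, the second component and the arrays left out together were chosen after seeing the data. Of 38 alternatives, 30 kept the count of all called probes within 1.5 times of 2410 and 33 kept the count of at least 2-fold within 1.5 times of 2062. The counts outside that range, for all probes and then for at least 2-fold, were 1174 and 1138 with the median as the scale, 971 and 971 within slide 1, and 0 and 0 within slide 2, where limma gave 2452 and 2276 at an unadjusted p under 0.05. Scaling to the E1A spike-in gave 10472 and 9218; its cutoff on the spike-in signal was first 100 and was raised to 256 after the values were seen, and with the first cutoff it gave 10089 and 8858. For all probes alone, array weights gave 4707, the no-target covariate 4085, and slide and slide row together as blocks 1471. Apart from the shift of the spike-in scale, the cause was not tested. Leaving out each array in turn gave 1817 to 2592 probes, and 1674 to 2219 of at least 2-fold. Without the 3 arrays bright at no-target probes limma called 2473, of which 1985 were called in the main comparison with the same sign, and without control replicate 3 as well it called 2683. Under normexp the median difference of all probes lay at 0.16 on the log2 scale, against -0.06. The first component's group difference of 10.6 passed the test under normexp (-49.7), in the authors' values (113) and among probes above background on all arrays (60.9). A component's sign is arbitrary, and the cause was not tested. The second component of the main values, a different axis, also passed (73.9). The difference in spread passed under 0 of 6 alternatives. The 4 named probes kept their direction in each alternative that gave a value, and lost their call only within slide 2, with 2 or 3 EE2 arrays, at adjusted p of 0.462 to 0.597 and log2 differences of 7.94, 7.49, -4.65 and -3.29 against 7.64, 7.35, -4.99 and -4.90 (smallest over all alternatives 2.91e-07). The alternatives for gene lists, for several probes of a gene and for relations among EE2 arrays were not run, since no probe has a gene name. Signal over background limits the comparison, since 10882 probes were too dim to be tested.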

Other observations

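The probes called as changed had a lower GC content than those tested, with medians of 38.3% for rises and 40% for falls against 43.3%. The loading of the first component also followed GC content. Whether probes rich in GC were harder to call for that reason was not tested. In 254 of the 331 pairs of tested probes with the same sequence and at least 1 call, both were called, all 254 with the same sign.

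A hypothesis written before its test was that EE2 fish differ in one common size of response, so that fish with larger rises also have deeper falls. Across the 8 EE2 arrays the mean deviations over 380 risers and 375 fallers of at least 2-fold had Pearson r = -0.048 (exact permutation p = 0.904, adjusted p = 1 over 2 relations) and Spearman rho = 0 (exact permutation p = 1). Without the 2 arrays farthest from the median r was -0.70 over 6 arrays, so the value rests on those arrays. With 8 arrays, 1 SE below the value reached r = -0.46, so a common size is neither borne out nor excluded. Among the controls the same relation had r = 0.19, and the deviations at risers spanned 0.830 log2 units, against 0.798 among the EE2 arrays. The range at risers was thus no larger among the EE2 fish than among the controls. The controls include replicate 3, which lay at a position of 0.343 toward the EE2 arrays over risers. Their range is therefore not a neutral measure of the spread between fish.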
